A study of Homo sapiens with 5 samples.

How the data were processed

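The measurements were total RNA levels in TE85 cells, an established human osteosarcoma cell line, hybridised to Affymetrix HGU133A arrays. A probe set on this platform is a group of short oligonucleotides, chosen mostly near the 3′ end of a transcript, that together give 1 signal. Each of 5 culture surfaces had 1 array, and all 5 samples were labelled as taken at 6 h. The surfaces were 3 with a conjugated amino acid (aspartic acid, glutamic acid, serine) and 2 controls, an amino-terminated surface and tissue culture polystyrene. The platform name came from the probe set names and a platform annotation table.

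The authors deposited 1 table of linear intensity values, with 22283 probe sets and 1 column for each of the 5 arrays. The software that summarised probes into probe sets, and the scaling, are not given in the sources used here. Per the deposited values, column medians lay between 93.7 and 95.7 and upper quartiles between 287 and 298, so the columns had been brought to a common scale. Detection calls, which would say whether a signal exceeded its background, were not used here. The table has no replicate arrays, so the number of arrays limits the precision of every value, and no difference has a replicate check.

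The 5 columns were quantile-normalized together with limma 3.58.1 in R 4.3.3. Values under the 40th percentile, a signal of 70.7, were set to that floor, and log2 was taken afterwards. Gene names came from the platform annotation, checked against current gene identifiers, with 0 symbols updated. Of the probe sets, 19071 had 1 gene symbol, 1043 had several and 2169 had none, and genes were named only from the first kind. Each of 11963 genes took the value of its probe set with the highest mean log2 signal. The 8631 genes whose mean lay above the floor are called measured. Other probe sets of a named gene were compared, and examples of disagreement are given with the gene.

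No test between surfaces was possible with 1 array each, so no p-value is given. A gene was counted as different where the floored log2 difference between a pair of arrays was at least 1, a 2-fold difference. Where 1 side lay at the floor, the fold is a lower bound. The counts cover the 10 pairs of arrays, the 3 amino acid arrays against both controls by the smallest gap, and each array against the other 4. For gene lists, the median log2 difference of the measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called set apart when its percentile was below 2.5 or above 97.5, and a list needed 5 measured genes. With 30 lists tested, 1.5 would be set apart by chance in each comparison if the members of a list varied independently. Members may vary together, which the random lists do not copy, so the number by chance could be higher. These percentiles describe the 5 arrays and are not tests of the surfaces.

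The 31 gene lists, the threshold, the floor, the rule for named genes and 5 processing alternatives were chosen before the data were examined. The rule named, in each pair, up to 8 genes each way among those 2-fold apart and measured on both sides, with no other probe set above the floor going the opposite way. It added the 3 largest lower bounds each way, and 10 genes each way for the 3 amino acid arrays against both controls and for each array against the other 4. It also named up to 4 members of each list described. COL1A1, SPP1, ALPL, FN1, RUNX2, FOS, EGR1, CCN1, CCN2, IL6, GAPDH and ACTB were named whatever their values.

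The 5 alternatives were median scaling, cyclic loess, a floor at the 20th or 60th percentile, and the mean of all probe sets of a gene. Arrays were also left out in turn from the comparison of the 3 amino acid arrays with both controls. After the data were seen, 3 more were added: the deposited values with no further scaling, a threshold of 1.5-fold, and removal from each probe set of its linear trend on the 5′ to 3′ signal ratio. That ratio compares the signal of probe sets at the 5′ and 3′ ends of the ACTB and GAPDH control transcripts, and falls when RNA is shortened or copied incompletely.

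The procedure was tested on simulated data for aspartic acid against polystyrene with 8631 genes. It recovered 0% of genes changed 1.5-fold, 71.6% of those changed 2.5-fold and 88.1% of those changed 4-fold, and called 0 of 8431 unchanged genes. The simulated noise was normal and independent between genes, with a shared standard deviation within each expression bin. It held no 5′ to 3′ trend and no disagreement between probe sets. The 0 calls therefore give no rate of false calls for the real arrays. Of 100 unchanged lists 5% were set apart, and of 100 lists shifted by 0.2 on the log2 scale 98% were. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for all steps after normalization. Probe sets without a single gene symbol were left out of the gene comparisons.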

Results

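Gene expression was measured in TE85 osteosarcoma cells on 5 culture surfaces at 6 h, with 1 array per surface. The amino acid surfaces carried aspartic acid, glutamic acid or serine, and the controls were an amino-terminated surface and tissue culture polystyrene. No surface had a replicate, so every difference below is between 2 arrays or sets of arrays and has no replicate check. Signals are quantile-normalized intensities in arbitrary units. Across all probe sets, log2 signals of any pair of arrays correlated with Pearson's r between 0.993 and 0.996, which is across probe sets and not across samples. Among the 8631 measured genes, the standard deviation of the log2 difference ranged from 0.16 for glutamic acid against amino-terminated to 0.21 for aspartic acid against amino-terminated.

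The arrays differed in the 5′ to 3′ signal ratio of control transcripts, a sign of RNA or labelling quality. The ACTB ratio was 0.25 on aspartic acid, 0.315 on serine, 0.479 on polystyrene, 0.592 on glutamic acid and 0.800 on amino-terminated. The GAPDH ratio had the same order, from 0.337 on aspartic acid to 0.720 on amino-terminated. The order did not follow the division into amino acid surfaces and controls. The 28S ribosomal RNA control signal also varied, from 780 on aspartic acid to 5700 on polystyrene. Of 79 differences in named genes, 42 stayed 2-fold in the same direction once the trend on this ratio was removed, 31 fell under 2-fold and 6 changed sign. Of 77 list results set apart, 56 stayed so.

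**Figure D1:**
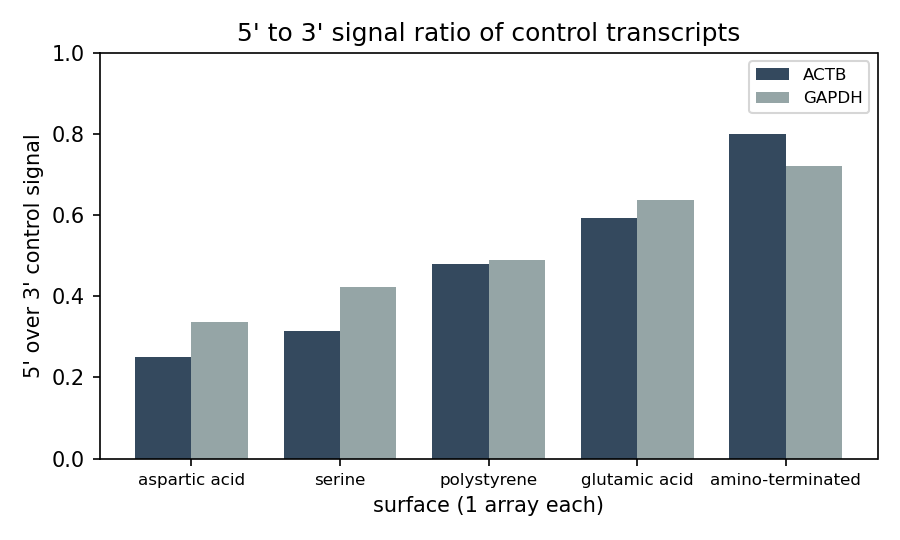
Ratio of 5′ to 3′ control signal (no unit, vertical axis from 0) for ACTB (dark bars) and GAPDH (light bars) on the 5 arrays, 1 array per surface with no error bars. Both ratios were lowest on aspartic acid (0.25 and 0.337) and highest on amino-terminated (0.800 and 0.720).

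The first question was how cells on each modified surface differed from cells on ordinary culture plastic. On all 4 modified surfaces, genes of the G2 and M phases of the cell cycle were higher than on polystyrene. The median log2 difference of the 30 measured genes was 0.21 on aspartic acid, 0.17 on amino-terminated, 0.14 on serine and 0.12 on glutamic acid, at percentiles of 99.96 or above. Of these 30 genes, 16 were higher on all 4 surfaces than on polystyrene, or 53.3%, against 17.6% of all measured genes. The mitotic kinesin KIF11 was 0.39 (log2) higher on aspartic acid and 0.52 higher on glutamic acid. TOP2A, the topoisomerase that untangles replicated DNA, was 0.48 higher on serine, and the kinetochore motor CENPE was 0.55 higher on amino-terminated. The 28S ribosomal RNA signal was 780 on aspartic acid, 928 on amino-terminated, 1379 on glutamic acid, 2378 on serine and 5700 on polystyrene. No G2 and M gene reached 1.5-fold, so the difference was small and spread over the list. The 4 comparisons share the polystyrene array and are not independent.

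Genes controlled by NRF2, the regulator of the response to oxidative stress, were also higher than on polystyrene. The median of 17 genes was 0.19 on glutamic acid, 0.17 on amino-terminated and 0.12 on aspartic acid, all set apart, and 0.08 on serine, at percentile 95.6. On aspartic acid the list was not set apart under all 5 alternatives. Of the 17 genes, 10 were higher on all 4 surfaces and 0 were lower on all 4. GCLM, a subunit of the enzyme that starts glutathione synthesis, had a signal of 339 on polystyrene and 485 to 792 on the other surfaces. It was 2.34-fold higher on glutamic acid and 2.07-fold higher on amino-terminated, where it fell to 0.73 (log2) with the 5′ to 3′ trend removed. The cystine transporter SLC7A11 was 0.79 higher (log2) on glutamic acid and 0.57 higher on amino-terminated. NQO1, a quinone reductase, was 0.53 higher on aspartic acid and 0.54 higher on glutamic acid.

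Genes of the actin and myosin cytoskeleton were lower than on polystyrene on all 4 surfaces. The median of 25 genes was -0.17 on serine, -0.11 on glutamic acid, -0.09 on amino-terminated and -0.07 on aspartic acid, each set apart, though on amino-terminated not under all 5 alternatives. The smooth muscle actin gene ACTA2 had a signal of 710 on polystyrene and 444 to 537 elsewhere. Of the list, 12 genes were lower on all 4 surfaces, or 48%, against 20.3% of all measured genes. Cholesterol synthesis genes were lower as well, with medians over 19 genes of -0.24 on amino-terminated, -0.17 on serine, -0.14 on glutamic acid and -0.08 on aspartic acid. HMGCS1, an early enzyme of this pathway, was at -0.58 on amino-terminated, and MVD was at -0.46 on serine. On serine this list was not set apart under all 5 alternatives, and on glutamic acid not with the 5′ to 3′ trend removed (percentile 2.78). With that trend removed the medians were -0.12 on amino-terminated, -0.13 on serine, -0.11 on glutamic acid and -0.13 on aspartic acid.

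**Figure D2:**
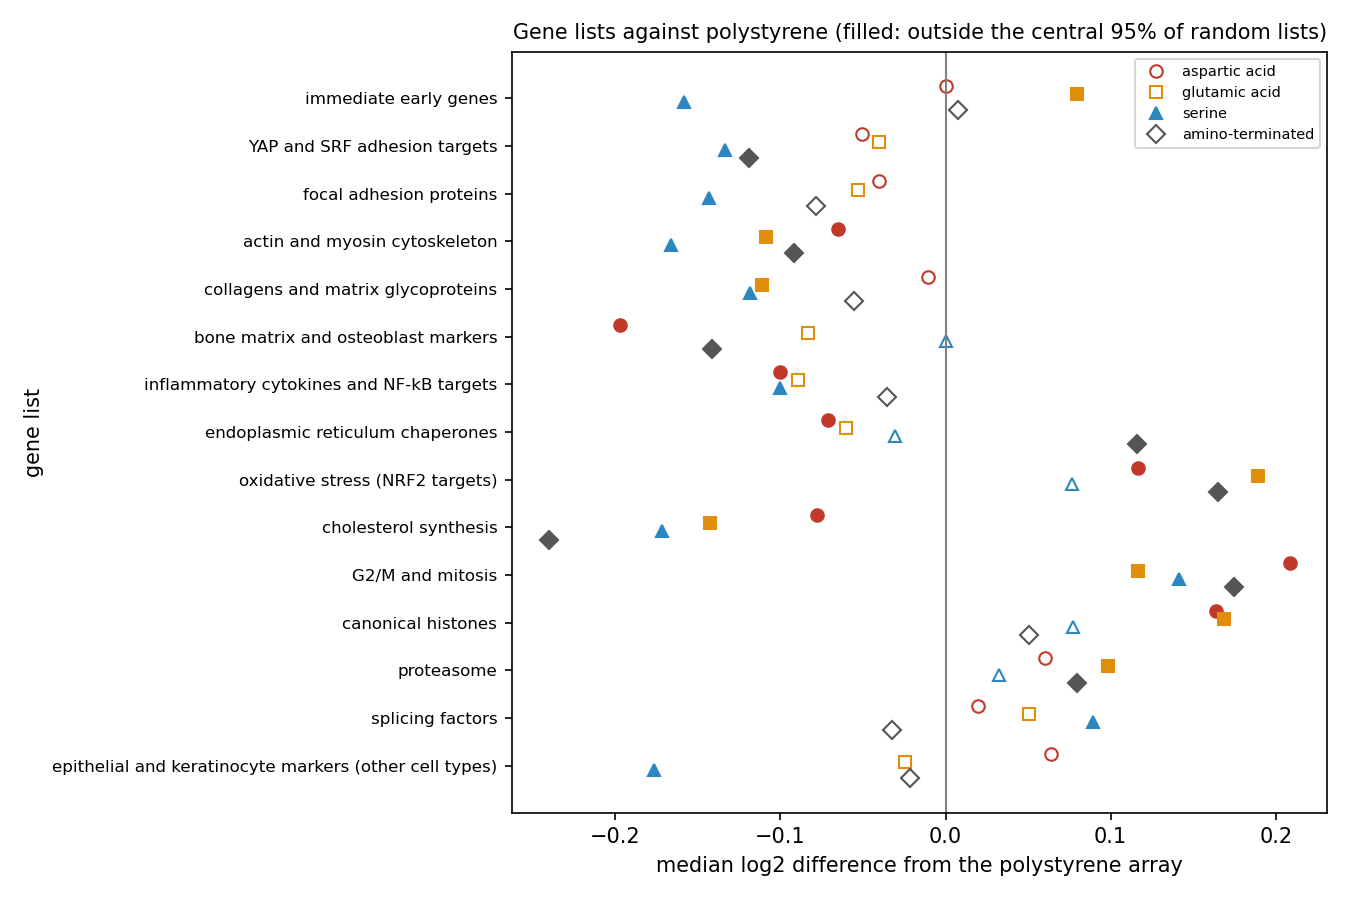
Median log2 difference from the polystyrene array (horizontal axis) of each gene list that was set apart for at least 1 surface, with 1 point per surface. Filled points lie outside the limits set by random lists matched on expression, as for the G2 and M genes on all 4 surfaces (0.12 to 0.21).

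Single genes stood apart from polystyrene on several surfaces. MMP1, the collagenase of fibrillar collagen, had a signal of 114 on polystyrene and 190 to 284 elsewhere, and was 2.48-fold higher on serine and 2.24-fold higher on amino-terminated. HES1, a transcriptional repressor induced by Notch, had a signal of 287 on polystyrene against 472 to 983. The folate receptor gene FOLR1 had a signal of 213 on polystyrene against 307 to 652. A second FOLR1 probe set near the floor barely differed, between 70.4 and 82.4 on the 5 arrays. IGFBP5, a binding protein of insulin-like growth factors, was at least 3.06-fold lower on each other surface than on polystyrene. That value rests on a single probe set with a signal of 217 on polystyrene and 24.7 to 27.3 elsewhere, and the other 4 IGFBP5 probe sets showed no such difference. With the mean of all probe sets, or with a floor at the 20th or 60th percentile, IGFBP5 was not 2-fold lower.

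On the aspartic acid surface, 12 genes differed 2-fold from polystyrene, 2 higher and 10 lower. HES1 was 3.43-fold higher, and the immediate early transcription factor EGR1 was 3.07-fold higher. The lower genes included several of the endoplasmic reticulum. GANAB, the catalytic subunit of glucosidase II, was 3.13-fold lower, PDIA3, a disulfide isomerase, was 2.82-fold lower, and SDF2L1 was 2.26-fold lower. The zinc transporter gene SLC39A7 was 2.26-fold lower, the lipid kinase gene PIP5K1A 2.23-fold lower, and the pro-apoptotic gene BAX 2.15-fold lower. ZWILCH, a kinetochore component, was 2.11-fold lower, and the chromatin remodeller gene HELLS 2.03-fold lower. HIRA, a histone chaperone, was at least 3.58-fold lower. The 18 endoplasmic reticulum chaperone genes had a median of -0.07 (percentile 0.83), and the 11 bone matrix and osteoblast genes a median of -0.20, below all 10000 random lists but not set apart under all 5 alternatives. The aspartic acid array had the lowest 5′ to 3′ ratio. With that trend removed, the chaperone genes were not set apart (-0.04, percentile 10.2), 7 genes differed 2-fold, PDIA3 was at -0.85 and GANAB at -0.92. ZWILCH and HELLS fell under 2-fold with median scaling, PIP5K1A and BAX with the mean of all probe sets, and BAX, SLC39A7 and HIRA with a floor at the 60th percentile.

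On the glutamic acid surface, 9 genes differed 2-fold from polystyrene, 6 higher and 3 lower. HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, was 4.28-fold higher, with a signal of 799 against 187. EGR1 was 3.49-fold higher, GCLM 2.34-fold, the stress-induced transcription factor gene ATF3 2.21-fold and FOLR1 2.21-fold higher. FOS, another immediate early gene, was at least 2.43-fold higher. The 21 measured immediate early genes had a median of 0.08 (percentile 98.3), which was not set apart under all 5 alternatives or with the 5′ to 3′ trend removed (percentile 94.6). CTSZ, a lysosomal protease gene, was 4.04-fold lower and the Wnt co-receptor gene LRP5 2.05-fold lower. A second CTSZ probe set read 85 to 92 on all 5 arrays. The 29 collagen and matrix glycoprotein genes had a median of -0.11, with BGN at -0.60, while THBS1, which encodes thrombospondin 1, was at 0.80 and LUM, which encodes lumican, at 0.77. That list was not set apart under all 5 alternatives. FOS and ATF3 fell under 2-fold with a floor at the 60th percentile, FOLR1 with the mean of all probe sets, and LRP5 under median scaling and with the 5′ to 3′ trend removed (-0.88).

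On the serine surface, 4 genes differed 2-fold from polystyrene: FOLR1 (3.07-fold), MMP1 (2.48-fold) and HES1 (2.15-fold) were higher, and IGFBP5 was lower. With the mean of all probe sets FOLR1 and HES1 fell under 2-fold, and HES1 also did with the 5′ to 3′ trend removed (0.82). More gene lists were set apart here than on the other 3 surfaces, 10 of 30, of which 8 were lower. The 18 focal adhesion genes had a median of -0.14 (percentile 0.02). TLN1, which encodes talin 1, the link between integrins and actin, had a signal of 292 against 541 and a log2 difference of -0.89. ZYX, which encodes zyxin, was at -0.42. Targets of YAP and SRF, transcription regulators that respond to adhesion and actin, had a median of -0.13 over 16 genes (percentile 0.15). Collagen and matrix glycoprotein genes had a median of -0.12 (percentile 0.01) and immediate early genes one of -0.16 (percentile 0.01), with JUNB at -0.45. These 4 lists were set apart under all 5 alternatives. Epithelial and keratinocyte markers, of another cell type, were lower too, with a median of -0.18 over 7 genes (percentile 0.72), though not under all 5 alternatives. Some genes, such as TAGLN and VCL, belong to more than 1 list.

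On the amino-terminated control, 4 genes differed 2-fold from polystyrene: MMP1 and GCLM were higher, and IGFBP5 and CTSZ were lower. MMP1 fell under 2-fold with a floor at the 60th percentile, and GCLM with the 5′ to 3′ trend removed (0.73). CTSZ is outside the rule for named genes, since its second probe set went the opposite way, and was chosen after its values were seen. Endoplasmic reticulum chaperone genes were higher, with a median of 0.12 over 18 genes (percentile 99.6) and PDIA6 at 0.51. The 5′ to 3′ ratio was also higher on this array (ACTB 0.800 against 0.479), and with its trend removed the median was -0.01. Bone matrix and osteoblast genes had a median of -0.14 (percentile 0.61), with TWIST1 at -0.30. YAP and SRF targets had a median of -0.12 (percentile 1.74). Neither of these last lists was set apart under all 5 alternatives.

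The second question was how the amino acid surfaces differed from the amino-terminated control. Aspartic acid differed 2-fold in 16 genes, 3 higher and 13 lower. Higher were FKBP10 (2.12-fold), a prolyl isomerase gene of collagen folding, HES1 (2.08-fold) and EGR1 (2.07-fold). Lower were TMEM230 (3.45-fold), GANAB (3.05-fold), PSAT1 (2.92-fold), an enzyme of serine synthesis, PDIA3 (2.84-fold), EIF2S3 (2.69-fold), a subunit of an initiation factor of translation, SDF2L1 and GPR176 (2.58-fold each) and NMD3 (2.29-fold), a ribosome export adaptor. These arrays lay at the ends of the 5′ to 3′ ratio, and PSAT1, TMEM230, EIF2S3, GPR176 and NMD3 followed its order over all 5 arrays. With the trend removed, 0 genes differed 2-fold, EGR1 was at 0.85, HES1 at 0.12 and TMEM230 at -0.04. FKBP10 (-0.17), PSAT1 (0.04) and EIF2S3 (0.00) then changed sign. GPR176 and NMD3 fell under 2-fold with a floor at the 60th percentile, and HES1 with the mean of all probe sets.

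By the mean log2 of the ACTB and GAPDH 5′ to 3′ ratios, glutamic acid (-0.70) and the amino-terminated control (-0.40) were the closest pair. Between them 5 genes differed 2-fold, all higher on glutamic acid. HMOX1 was 3.94-fold higher, HIRA 2.51-fold, FOS 2.40-fold, EGR1 2.36-fold and ATF3 2.24-fold higher. Each stayed at least 2-fold higher with the ratio's trend removed. With a floor at the 60th percentile, FOS and ATF3 fell under 2-fold and 3 genes remained past the threshold. A second EGR1 probe set read 570 on glutamic acid and 199 on amino-terminated. The 21 immediate early genes had a median of 0.08 (percentile 98.6), with 18 above 0, which was not set apart under all 5 alternatives.

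Serine differed from the amino-terminated control 2-fold in 9 genes, 5 higher and 4 lower. Higher were CTSZ (4.09-fold), GOLIM4 (2.74-fold), a Golgi protein gene, WASL (2.15-fold), a regulator of actin branching, SECISBP2L (2.12-fold) and BAX (2.02-fold). Lower were TMEM230 (2.43-fold), PSAT1 (2.42-fold) and SELENOT (2.12-fold). The fourth lower gene, EIF5A, was outside the rule because another of its probe sets went the opposite way, and was chosen after its values were seen. Second probe sets of GOLIM4 (77.9 against 70.2) and SECISBP2L (147 against 135) differed less. With the mean of all probe sets GOLIM4, WASL, SECISBP2L and BAX fell under 2-fold, and BAX also did under median scaling and cyclic loess. These arrays also differed in 5′ to 3′ ratio (ACTB 0.315 against 0.800). With the trend removed 2 genes differed 2-fold, CTSZ was at 0.82, PSAT1 at -0.04, and TMEM230 changed sign to 0.07.

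Endoplasmic reticulum chaperone genes were lower on each amino acid surface than on the amino-terminated control. The median over 18 genes was -0.21 on aspartic acid, -0.20 on glutamic acid and -0.19 on serine, each below all 10000 random lists and set apart under all 5 alternatives. On glutamic acid, PDIA4 was at -0.46 and MANF at -0.38. On serine, SEL1L was at -0.47 and HYOU1 at -0.39. The amino-terminated array had the highest 5′ to 3′ ratio, and with its trend removed the medians were -0.07 on aspartic acid, -0.15 on glutamic acid and -0.02 on serine, the last at percentile 46.4. NRF2 targets were lower on aspartic acid than on amino-terminated, with a median of -0.17 (percentile 0.02), which changed sign to 0.05 with the trend removed.

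The amino acid surfaces were also compared with each other at the same time of 6 h. The side chains of aspartic and glutamic acid both end in a carboxyl group and differ in length by 1 methylene group, while serine carries a hydroxyl group. Aspartic acid differed from glutamic acid 2-fold in 16 genes, 3 higher and 13 lower. HMOX1 was 3.79-fold lower on aspartic acid, GANAB 3.43-fold, PDIA3 3.12-fold, TMEM230 2.58-fold, EIF2S3 2.48-fold, ZWILCH 2.31-fold, PSAT1 2.29-fold and NMD3 2.19-fold lower. HIRA was at least 5.02-fold lower, while FKBP10 was 2.98-fold and CTSZ 2.22-fold higher. NRF2 targets had a median of -0.19, below all 10000 random lists and set apart under all 5 alternatives. With the 5′ to 3′ trend removed, 2 genes differed 2-fold, HMOX1 (-1.44) and HIRA (-1.66), the median of the NRF2 targets was -0.04 (percentile 6.16), and CTSZ (-0.02) and PSAT1 (0.00) changed sign. CTSZ and NMD3 fell under 2-fold with a floor at the 60th percentile, and CTSZ also did with the mean of all probe sets.

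Both acidic surfaces differed from serine in immediate early genes. The median over 21 genes was 0.31 for glutamic acid against serine and 0.24 for aspartic acid against serine, each at percentile 100 and set apart under all 5 alternatives. The serine array was itself low in this list, at -0.16 against polystyrene and -0.08 against amino-terminated. Glutamic acid was at 0.08 against each control, not set apart under all 5 alternatives, and aspartic acid was set apart from neither control. The list difference therefore came in good part from serine. EGR1 was 3.02-fold higher on glutamic acid and 2.66-fold higher on aspartic acid than on serine. ATF3 read 155 on aspartic acid and 209 on glutamic acid, against 93.4 to 101 on the other 3 surfaces. Against serine, glutamic acid differed 2-fold in 6 genes. HMOX1 (3.37-fold), FOS (at least 2.43-fold) and ATF3 (2.08-fold) were higher as well, and CTSZ (5.43-fold) and FKBP10 (2.03-fold) were lower. FKBP10 fell short of 2-fold under median scaling and with the 5′ to 3′ trend removed (-0.35), and FOS and ATF3 did with a floor at the 60th percentile. YAP and SRF targets were higher on glutamic acid than on serine, with a median of 0.16 (percentile 99.96), CCN2 at 0.65 and THBS1 at 0.93. NRF2 targets had a median of 0.17 (percentile 99.98), which was 0.10 (percentile 99.4) with the 5′ to 3′ trend removed.

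Aspartic acid differed from serine 2-fold in 12 genes, 1 higher and 11 lower, on arrays with similar 5′ to 3′ ratios (ACTB 0.25 and 0.315). PDIA3 was 2.86-fold lower, GANAB 2.80-fold, BAX 2.71-fold, ZWILCH 2.52-fold, CTSZ 2.44-fold, PIP5K1A 2.33-fold, SLC39A7 2.24-fold and GNL3L 2.19-fold lower. HIRA was at least 3.94-fold lower. Each of these named genes stayed at least 2-fold lower with the 5′ to 3′ trend removed. BAX, CTSZ, PIP5K1A and GNL3L fell under 2-fold with the mean of all probe sets, and SLC39A7 and GNL3L with a floor at the 60th percentile. Focal adhesion genes were higher on aspartic acid, with a median of 0.16 (percentile 99.9), and so were collagen and matrix glycoprotein genes, at 0.11 (percentile 99.3). Neither list was set apart under all 5 alternatives. With 1 array per surface, no interval can be given for any difference between these related molecules, so neither a difference nor its absence is established beyond these arrays.

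No gene was 2-fold higher or lower on all 3 amino acid surfaces than on both controls. The genes with the widest gap were FBXO11, a ubiquitin ligase subunit, at 0.49 (log2) and SNAPC1 at 0.40, followed by SHCBP1 (0.34), ZNF124 (0.33) and RB1 (0.33), the retinoblastoma tumour suppressor gene. FBXO11 read 513 to 683 on the amino acid surfaces and 346 and 366 on the controls. The largest gaps downwards were SLC25A22 (-0.27) and TLN1 (-0.22). Of the 30 lists 8 were set apart, 5 higher and 3 lower on the amino acid surfaces. Canonical histone genes had a median of 0.14 over 7 genes (percentile 99.6), set apart under all 5 alternatives and with the 5′ to 3′ trend removed (percentile 99.3). Endoplasmic reticulum chaperone genes had a median of -0.17 (below all random lists), actin and myosin genes -0.05 and focal adhesion genes -0.05, each set apart under all 5 alternatives. Against single controls, however, the actin and myosin list was set apart only from polystyrene, and there also on the amino-terminated control (-0.09). The focal adhesion list was set apart from a single control only for serine against polystyrene (-0.14). Neither list therefore separated all 3 amino acid surfaces from both controls. The chaperone difference came mainly from the amino-terminated array, since against polystyrene the medians were -0.07 on aspartic acid, -0.06 on glutamic acid and -0.03 on serine, the last 2 not set apart. With the 5′ to 3′ trend removed the chaperone median was -0.04 (percentile 3.22).

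Single arrays that differed 2-fold from all 4 others did so in few genes. On aspartic acid these were PDIA3 (-1.50), GANAB (-1.49) and ZWILCH (-1.07), all lower. PDIA3 read 769 on aspartic acid and 2168 to 2399 elsewhere. Both GANAB probe sets were lowest on aspartic acid, at 453 and 540 against at least 1272 and 1032 on the others. PDIA3 and ZWILCH had 1 measured probe set each. With the 5′ to 3′ trend removed, 0 genes stood apart on aspartic acid. That array lay at the low end of the ratio, so by construction the trend takes up part of its own difference. Against serine, the array next in ratio, PDIA3 was still at -1.25, GANAB at -1.18 and ZWILCH at -1.16 with the trend removed. On glutamic acid HMOX1 was 3.37-fold above the next array, and FOS was at 0.96 (log2). Serine and amino-terminated had 0 such genes. On serine the widest gaps were RPL27A (0.66) and GOLIM4 (0.53) upwards, and EPB41L3 (-0.49), HBEGF (-0.48) and RHOB (-0.48) downwards. On polystyrene IGFBP5 stood apart through the single probe set described above.

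**Figure D3:**
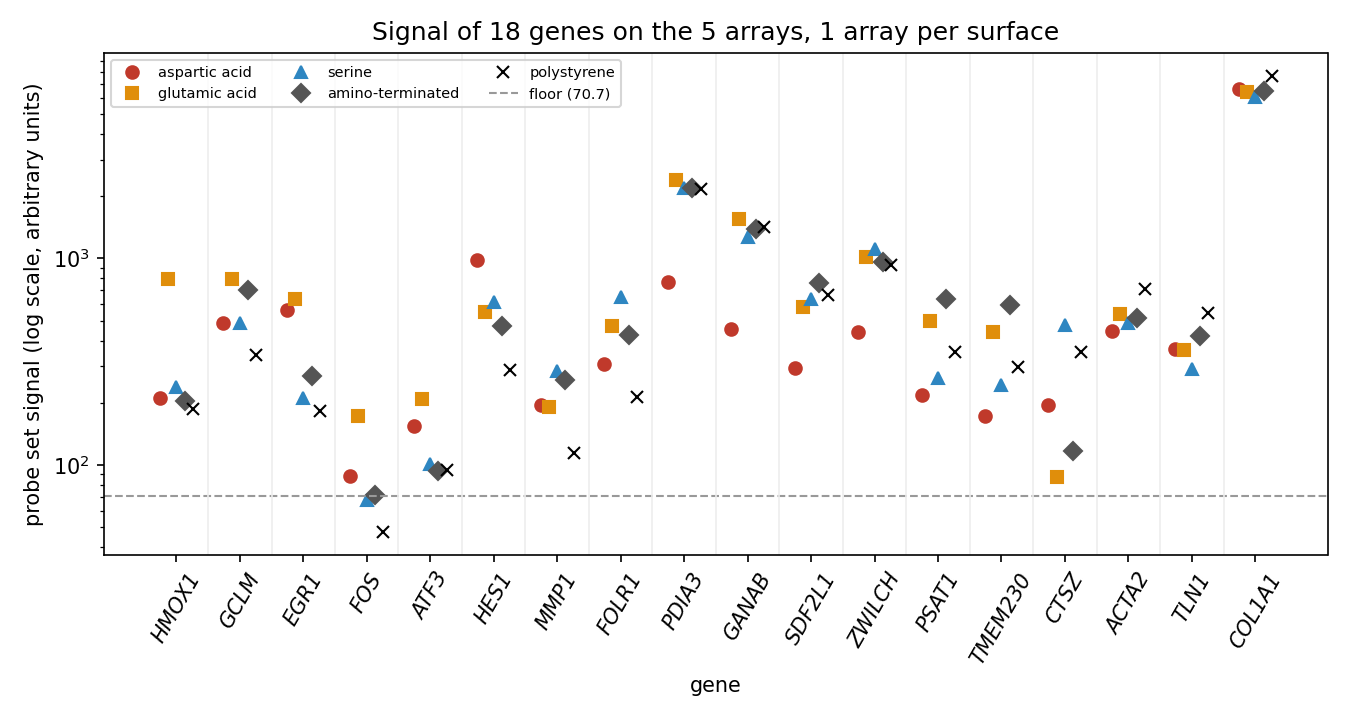
Quantile-normalized signal (arbitrary units, logarithmic vertical axis) of 18 genes on the 5 arrays, with 1 point per array and no error bars. HMOX1 was highest on glutamic acid (799 against 187 to 237), and PDIA3 was lowest on aspartic acid (769 against 2168 to 2399), while the dashed line marks the floor of 70.7.

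By the brightest probe set, none of the bone and adhesion genes fixed beforehand differed 2-fold between any pair of arrays. COL1A1, the main collagen of bone, read 7659 on polystyrene and 6046 to 6619 elsewhere, with log2 differences from -0.34 on serine to -0.21 on aspartic acid. A dimmer COL1A1 probe set read 326 on aspartic acid, 656 on polystyrene and 753 on amino-terminated. SPP1, which encodes osteopontin, and IL6 were at the floor on all 5 arrays, and ALPL, which encodes alkaline phosphatase, was above it on amino-terminated alone (76.5). RUNX2, the osteoblast transcription factor gene, read 94.2 to 108. FN1, which encodes fibronectin, was at -0.53 on serine and -0.48 on aspartic acid against amino-terminated. CCN1 read 1731 to 1981 and CCN2 1418 to 2232, with CCN2 at -0.64 on serine against amino-terminated, where 0.5% of all measured genes lay below -0.62. A second CCN1 probe set ranged more widely, from 806 on aspartic acid to 1774 on amino-terminated, in the order of the 5′ to 3′ ratio over all 5 arrays. FN1, CCN2 and the dimmer COL1A1 probe set also read lowest on aspartic acid and serine, the arrays with the lowest ratios. GAPDH read 13717 to 16059. ACTB held the top rank on all arrays, which quantile normalization sets to 1 value (17201), so it carries no information on differences.

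Several lists were set apart in none of the comparisons. Their medians ranged from -0.05 to 0.04 for integrins, -0.05 to 0.07 for matrix proteases and inhibitors, -0.03 to 0.03 for heat shock proteins, and -0.07 to 0.09 for metallothioneins. They ranged from -0.01 to 0.05 for hypoxia and glycolysis, -0.07 to 0.08 for ribosomal proteins, -0.05 to 0.09 for oxidative phosphorylation, -0.02 to 0.06 for housekeeping genes and -0.07 to 0.02 for leukocyte markers. Of the endothelial markers only 4 genes were measured, too few for a value. The 7 epithelial and keratinocyte markers ranged from -0.18 to 0.22 and were set apart in 3 comparisons, all with serine, where they were lower. The 10 adipocyte, muscle and neural markers ranged from -0.13 to 0.02 and were set apart in 2 comparisons, both against amino-terminated.

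Agreement between probe sets of the same gene was limited. For 2479 genes with at least 2 measured probe sets, the correlation of their log2 differences across genes ranged from 0.07 for serine against amino-terminated to 0.48 for glutamic acid against polystyrene. Of 45 such genes that differed 1.5-fold between aspartic acid and amino-terminated by the brightest probe set, 24 had a second probe set of the same sign. For glutamic acid against polystyrene the number was 21 of 26.

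Differences against a shared control were correlated across the 8631 measured genes, which are not independent replicates. Simulated surfaces with no effect gave r of 0.50 because they share the control array. Independent differences of equal size between all arrays, from any source, would give the same r. The simulated values are therefore a reference for an even spread of the arrays and do not test for an effect. Pairs above or below them show only which arrays lay closer to each other. Glutamic acid and amino-terminated against polystyrene gave 0.68, with a covariance of 0.0259 against 0.0183 simulated. Aspartic acid and serine against amino-terminated gave 0.63, with a covariance of 0.0277 against 0.0181. The other 7 pairs lay between 0.32 and 0.48, with covariances below the simulated ones. In both pairs above the simulated value, the joined surfaces were neighbours in 5′ to 3′ ratio, but aspartic acid and serine against polystyrene gave 0.48, below it. The control is 1 array and cannot be split, so part of any excess may come from it.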

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

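The alternative scaling with the deposited values, the removal of the 5′ to 3′ trend and the 1.5-fold threshold were chosen after the results were seen, and the others were planned. No paired analysis was possible because each surface has 1 array. Of 79 named gene differences, 43 stayed at least 2-fold in the same direction under all 5 of those fixed beforehand, and of 77 list results set apart, 33 stayed so. The deposited values moved 0 of 36 counts and correlations by more than 1.5 times or, for correlations, 0.1. The G2 and M medians against polystyrene stayed between 0.10 and 0.28 under the 5 alternatives. Of the 79 named differences, 20 fell under 2-fold with a floor at the 60th percentile, 19 with the mean of all probe sets, 5 under median scaling, 4 with a floor at the 20th percentile and 1 under cyclic loess.

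The cause was not tested for the following changes, except where stated. Leaving out arrays gave 0 to 1 genes for the 3 amino acid surfaces against both controls, with 1 (EGR1, higher) without serine and 1 (IGFBP5, lower) without amino-terminated. Under median scaling, 1 list was set apart for aspartic acid against glutamic acid, against 3. Under cyclic loess, 5 genes stood apart on aspartic acid, against 3. A floor at the 60th percentile gave 2 genes for amino-terminated against polystyrene, 3 for glutamic acid against amino-terminated and 0 on polystyrene alone. It set apart 5 lists for aspartic acid against polystyrene and 3 for serine against amino-terminated, and the interferon median of the amino acid surfaces moved to 0.00057. A floor at the 20th percentile gave 0 genes on polystyrene alone, 5 lists for aspartic acid against polystyrene and 3 for serine against amino-terminated. The floors differ by construction in how many dim genes can differ. The mean of all probe sets gave 2 genes for amino-terminated against polystyrene, 1 for serine against polystyrene, 5 for serine against amino-terminated, 7 for aspartic acid against serine and 0 on polystyrene alone. It set apart 5 lists for amino-terminated against polystyrene, 6 for aspartic acid against glutamic acid and 4 for aspartic acid against serine, and moved the median of amino acid response genes on the amino acid surfaces to -0.0114.

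Removing the 5′ to 3′ trend gave 7 genes for aspartic acid against polystyrene, 0 against amino-terminated and 2 against glutamic acid, 2 for serine against amino-terminated and 0 on aspartic acid alone. It set apart 9 lists for aspartic acid against amino-terminated and 5 against glutamic acid. Medians that changed sign were chaperones for amino-terminated against polystyrene (-0.0110), NRF2 targets for aspartic acid against amino-terminated (0.0459) and G1/S genes on the amino acid surfaces (-0.0059). Genes that changed sign were FKBP10 (-0.17), PSAT1 (0.0378) and EIF2S3 (0.0024) for aspartic acid against amino-terminated, TMEM230 (0.0703) for serine against amino-terminated, and CTSZ (-0.0219) and PSAT1 (0.00021) for aspartic acid against glutamic acid. Against polystyrene the correlations moved to 0.777 (aspartic and glutamic acid), 0.880 (aspartic acid and amino-terminated), 0.636 (glutamic acid and serine) and 0.661 (serine and amino-terminated). Against amino-terminated they moved to 0.622 (aspartic and glutamic acid) and -0.426 (aspartic acid and serine). A line through 5 arrays is set mostly by the arrays at its ends, so by construction this removes most of what separates aspartic acid from amino-terminated, whatever its source.

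At 1.5-fold the counts against polystyrene were 60 for amino-terminated, 56 for aspartic acid, 83 for glutamic acid and 23 for serine. Against amino-terminated they were 127, 21 and 128 for aspartic acid, glutamic acid and serine. Between amino acids they were 104 for aspartic against glutamic acid, 52 for aspartic acid against serine and 82 for glutamic acid against serine. Alone, aspartic acid had 17, glutamic acid 3, serine 1, amino-terminated 1 and polystyrene 4 genes. Scaling moved some splits of higher and lower genes by over 10 points. For amino-terminated against polystyrene, 2 and 2 became 4 and 2 under median scaling, cyclic loess and the deposited values. For serine against amino-terminated, 5 and 4 became 4 and 5 under the same settings. For aspartic acid against polystyrene, 2 and 10 became 3 and 8 under median scaling. For glutamic acid against serine, 4 and 2 became 4 and 1 under median scaling and the deposited values.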

Other observations

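The tests of the genes higher on glutamic acid and of the G2 and M genes were chosen after the results were seen, and so was the removal of the 5′ to 3′ trend. Canonical histone genes, of which 7 were measured, were higher on glutamic acid than on either control, with medians of 0.17 against polystyrene (percentile 99.54) and 0.15 against amino-terminated (percentile 99.52). H2BC21 was at 0.77 and H1-2 at 0.75 against polystyrene. Only the second median was set apart under all 5 alternatives. Proteasome genes were higher than on polystyrene on glutamic acid (0.10 over 24 genes) and amino-terminated (0.08), with PSMC3 at 0.52 and 0.62, and neither median was set apart under all 5 alternatives. Both arrays had higher 5′ to 3′ ratios than polystyrene, but with the trend removed the medians stayed set apart, at 0.09 and 0.10. PSMC3 itself followed the order of the ratio over all 5 arrays, at -0.30 on aspartic acid against polystyrene. Splicing factor genes were higher on serine than on polystyrene (0.09 over 25 genes), with TRA2B, a regulator of splice site choice, at 0.35, which did not hold under all 5 alternatives.

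Genes of the BMP and TGF-beta response had a median of 0.12 over 13 genes for glutamic acid against serine (percentile 99.3), set apart under all 5 alternatives, with the receptor gene TGFBR2 at 0.48. The arrays differed in 5′ to 3′ ratio (ACTB 0.592 against 0.315), and with its trend removed the list was not set apart (0.08, percentile 95.5). Inflammatory and NF-kB genes had medians of -0.10 on both aspartic acid and serine against polystyrene, and 0.10 for glutamic acid against amino-terminated, where TNFAIP3 was at 0.50 and CXCL8 at 0.39. With a floor at the 20th percentile the median on aspartic acid was 0.00678, and with the trend removed it was not set apart (percentile 7.16). The p53 targets had a median of 0.10 for glutamic acid against amino-terminated, with PMAIP1 at 0.66. Interferon response genes had a median of 0.14 for aspartic acid against amino-terminated (percentile 98.96), with IFITM1 at 0.48. With the trend removed that median was 0.05 (percentile 98.5). Amino acid response genes had a median of 0.08 for glutamic acid against amino-terminated, with MTHFD2 at 0.39, and G1/S genes one of 0.11 for serine against amino-terminated, with RRM1 at 0.52, which fell to 0.00384 with the trend removed. None of these lists apart from the BMP and TGF-beta response was set apart under all 5 alternatives in the comparisons named.

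Genes that differed between aspartic acid and amino-terminated may follow RNA or labelling quality. Of 230 genes with a log2 difference of at least 0.5, 112 (48.7%) had the other 3 arrays in the order of the 5′ to 3′ ratio. That order was read from control probe sets of these same arrays, so the test was not independent of the data. The share was 20.6% among all measured genes, and 16.7% is the chance value for a single gene. The genes were read on the same arrays and may vary together, so they are not independent draws. A single shared difference between arrays, of any source, could give many of them the same order, which may match the ratio's by chance. The share therefore leaves RNA or labelling quality open and does not decide for it. The coating as the study groups it would place serine and glutamic acid nearer to aspartic acid, and polystyrene nearer to amino-terminated. Only 7.39% of the genes (17) had that arrangement, against 8.83% of all measured genes. The chance value for a single gene is 12.5%, with the same limit. So low a share argues against the shared coating as the main source for these genes, whatever the chance value. A part specific to aspartic acid, such as GANAB on both probe sets, stays open.

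HMOX1, FOS, EGR1 and ATF3 were higher on glutamic acid than on serine and both controls. EGR1, ATF3 and FOS also read higher on aspartic acid (561, 155 and 88.5) than on those 3 arrays, and only HMOX1 was 2-fold above all 4 others. With the 5′ to 3′ trend removed the lowest HMOX1 difference was 1.41, which argues against that trend as its whole cause. The lowest difference of FOS, EGR1 and ATF3 was then 1.13, for ATF3 from amino-terminated, against 1.16 before. Differences of these genes moved both ways: from serine, FOS went from 1.28 to 1.20 and EGR1 from 1.59 to 1.70. The lowest is past 2-fold by less than the standard deviation of all measured genes (0.20), so for FOS, EGR1 and ATF3 the trend stays open. A fault of a single probe set is argued against for EGR1, whose second probe set differed by 1.52 from amino-terminated, but for HMOX1, FOS and ATF3, with 1 probe set each, it stays open, as the other 18 immediate early genes had a median of 0.08, at percentile 97.9. With 1 array per surface, a difference between cultures or their handling cannot be told apart from the coating.

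For the lower G2 and M genes on polystyrene, the lowest percentile of the 4 medians was 99.98 with the 5′ to 3′ trend removed. Polystyrene lay in the middle of the ratio's order, so this removal could hardly undo a difference from all 4 surfaces. A steady trend on the ratio would place the list on opposite sides of polystyrene. It was higher on the arrays with lower ratios (0.21 and 0.14) and on those with higher ratios (0.12 and 0.17). These values argue against such a trend. Over the 3 other scalings and 4 surfaces, the lowest percentile was 99.96. A scaling moves the list and its expression-matched random lists nearly alike. That percentile could therefore hardly change, and nothing is concluded from it about scaling. The 28S ribosomal RNA signal stays open: it was highest on polystyrene, and over the other 4 surfaces its Spearman correlation with the list median was -0.8, on too few arrays to decide. A difference in cell density or growth between dishes could give the same pattern and cannot be told apart from the surface with 1 array each.

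For the count of genes 2-fold apart on all 3 amino acid surfaces, 10 of 10 splits of the 5 arrays into 3 and 2 gave as many genes. The real value was 0, which every split must reach, so the count tests nothing. The highest of the other splits was 1, and 10 splits are too few for a share under 0.05. The split of glutamic acid and amino-terminated from the other 3 arrays gave the most genes at a gap of 0.5, 12, against 0 for the study's grouping. Some split must give the most, and the genes were read on the same arrays, so nothing is concluded from this about what groups the arrays. Glutamic acid and amino-terminated also had the highest 5′ to 3′ ratios. The split of aspartic acid and serine, also neighbours in 5′ to 3′ ratio, gave 1.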
